A study of Homo sapiens with 2 samples.

How the data were processed

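Total RNA from the lamina cribrosa region of the human optic nerve was measured on Affymetrix U133A 2.0 arrays, with 1 array for a normal nerve and 1 array for a glaucomatous nerve, per the labels. The labels do not say whether an array holds RNA of a single donor or of a pool. The deposited table gives the authors' processed signal intensity for 22277 probe sets on each array, on a linear scale and with no value at or below 0. After trimming 2% of the values at each end, the mean deposited intensity was 500.2 on the normal array and 500.1 on the glaucoma array, so the authors' values were scaled per array to one trimmed mean. The software, the background step and any detection calls are not given in the sources used here. The median intensity was 162.9 on the normal array and 344.6 on the glaucoma array, so scale was shared only at the trimmed mean.

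Probe sets were named through the annotation of the array platform, and symbols were updated through the gene identifier against the gene table of assembly GRCh38.p14, which was used for names only. Of the probe sets, 62 were array controls and 52 belonged to XIST or Y-linked genes, and both kinds were left out of all gene values. Of the rest, 19033 had 1 symbol, 1022 had several and were not named, and 2108 had no symbol in the table used here. The identifier gave the current symbol for 19021 probe sets. Each gene was represented by the probe set with the highest mean signal over both arrays, which gave 11939 genes. A gene was kept when its signal reached the array's median on at least 1 of the 2 arrays, which left 8662 genes.

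The value per gene was the log2 ratio of glaucoma over normal after adding a pseudocount of 72.2 signal units, the 25th percentile of the pooled signals, centred on the median over the kept genes. The median before centring was 0.16, so ratios are relative to that shift, and the pseudocount understates the ratios of dim genes. With 1 array per group there is no spread between people and no test of a gene, and the number of arrays limits the precision. The error given is the disagreement of probe sets of 1 gene on this pair of arrays. Over 5426 pairs of kept probe sets from 2628 genes, the SD of the difference was 1.54 log2 units, which corresponds to an SD of 1.09 log2 units, or 2.13-fold, for 1 probe set.

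Before the data were examined, 42 gene lists were fixed (markers of cell types of the optic nerve and neighbouring tissues, matrix, immune, stress and metabolic genes, and genes linked to glaucoma). For the 39 lists with at least 4 kept members, the median log2 ratio was placed among 10000 random lists of the same size matched on mean signal in 20 bins. A list was said to stand apart at a percentile of at most 2.5 or at least 97.5. This percentile describes these 2 arrays and is not a p-value. Chance alone would put 1.95 of 39 lists apart if genes varied independently. Genes of the same list can vary together between any 2 samples, and some lists share genes, so more lists could stand apart by chance.

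The genes named in the text follow a rule that was also fixed beforehand. It takes the 15 largest positive and 15 largest negative log2 ratios among kept genes whose brighter signal was at or above the 75th percentile of its array. These had to be at least 2-fold in the same direction as deposited, after quantile and after loess normalisation, with every other kept probe set of the same sign. It also takes the 4 kept members of each list with the largest ratio in either direction. GFAP, MBP, AQP4, MYOC, OPTN, NEFL, HBB, ACTB and GAPDH were to be named in every case, and a further gene of this part of the rule is not reported here.

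Each result was computed again under 10 alternatives, 1 of them chosen after seeing the data. They were the values as deposited without centring, quantile normalisation, a loess fit on mean signal with a span of 0.30, no pseudocount, a pseudocount of 252.3 at the median signal, no filter, a filter at the 75th percentile, the median of all probe sets of a gene, and probe sets without a cross-hybridisation suffix. A cross-hybridisation suffix there means any lettered suffix, such as s_at or x_at. The alternative added later raised all signals below the array median to it. The calculation was tested on simulated data modelled on the comparison of glaucoma with normal, with 7401 kept genes, a trend with signal and a noise SD of 0.30 log2 units, which is smaller than the probe set error of the real arrays. The changed genes were drawn only from those at or above the 75th percentile of an array, with all their kept probe sets shifted together. Of these, 94.0% of genes raised by 2 log2 units and 92.0% of genes lowered by 2 log2 units passed 2-fold. Changes in dimmer genes were not simulated. For changes of 1 log2 unit the shares were 24.0% and 68.0%. Among unshifted random lists 4.0% stood apart, and 100.0% of lists shifted by 1 log2 unit did. That shift was added to the finished log2 ratios, so the 100.0% does not test the pseudocount, the filter or the choice of probe set. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.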

Results

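The lamina cribrosa is the sieve of connective tissue and glia through which the axons of retinal ganglion cells leave the eye, and it is a site of damage in primary open-angle glaucoma (POAG). RNA from this region was profiled on 1 array for a normal optic nerve and 1 array for a glaucomatous one, and the comparison asks how expression differed between them. There were no replicates, so the values below describe these 2 arrays and no difference could be tested against the spread between people. Signals are the deposited intensities, and log2 ratios are glaucoma over normal with the pseudocount and centring given above. The probe set error, pooled over genes in the main setting, was 1.09 log2 units (SD) for 1 probe set. It is not the error of each ratio, as it depends on signal and setting and leaves out error shared by a whole array. The SD of the difference between probe sets was 1.54 in the main setting. It was 1.35 with the filter at the 75th percentile and 2.24 without a pseudocount.

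Oligodendrocyte and myelin genes, microglia and macrophage genes and MHC class II genes were lower on the glaucoma array than genes of similar brightness, and the kept T and B cell genes were higher. Each call has a limit. The myelin list did not stand apart without suffixed probe sets, the microglia list with the median of all probe sets, or the MHC class II list after quantile normalisation or loess. Of the 8 kept T and B cell genes, 7 passed the filter through the glaucoma array alone, and without the filter the list lay at percentile 96.55 of draws from genes of unrelated organs, short of the bound set beforehand. Among kept genes, 2400 of 8662 were at least 2-fold higher on the glaucoma array and 1853 were at least 2-fold lower, with 981 and 392 past 4-fold. After loess, 259 were past 4-fold higher and 680 lower, and after quantile normalisation 591 and 521, so the balance depends on the scaling. The 2-fold bound of 1 log2 unit is smaller than the probe set error of 1.09, so that error alone can carry a gene past it. The SD of the ratios over all kept genes was 1.38. Under all 4 scalings, 1477 genes were at least 2-fold higher and 1096 at least 2-fold lower. The astrocyte genes GFAP and AQP4 had ratios of -2.52 and -2.23, but astrocyte markers as a group were no lower than other genes of their brightness. Of the 39 gene lists with enough kept members, 4 stood apart from random lists matched on signal, where chance would give 1.95 if genes varied independently.

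The ratio depended strongly on brightness. In the dimmest 10% of kept genes by mean signal the median log2 ratio was 1.67, and in the brightest 10% it was -0.96. The filter contributes to the high ratios of dim genes. In the dimmest 10% the median signal was 52.0 on the normal and 349.7 on the glaucoma array. The array medians were 162.9 and 344.6, so many of these genes were kept through the glaucoma array alone. Across probe sets the Spearman correlation of the arrays was 0.616, over probe sets that are not independent replicates. Pairs of probe sets of the same gene had the same sign in 62.0% of 5426 pairs from 2628 genes (95% interval 60.4 to 63.7 from resampling whole genes), against 55.2% for pairs of different genes matched on signal. The highest signal of the bacterial trpn control, which is not among the usual spike-ins, was 29.1 on the normal and 198.5 on the glaucoma array, and ratios with a signal below it are not exact. The control's other probe sets read 2.4 and 21.3 on the normal array and 75.2 and 40.0 on the glaucoma array. In the main setting, list medians are given with their percentile among matched random lists.

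**Figure D1:**
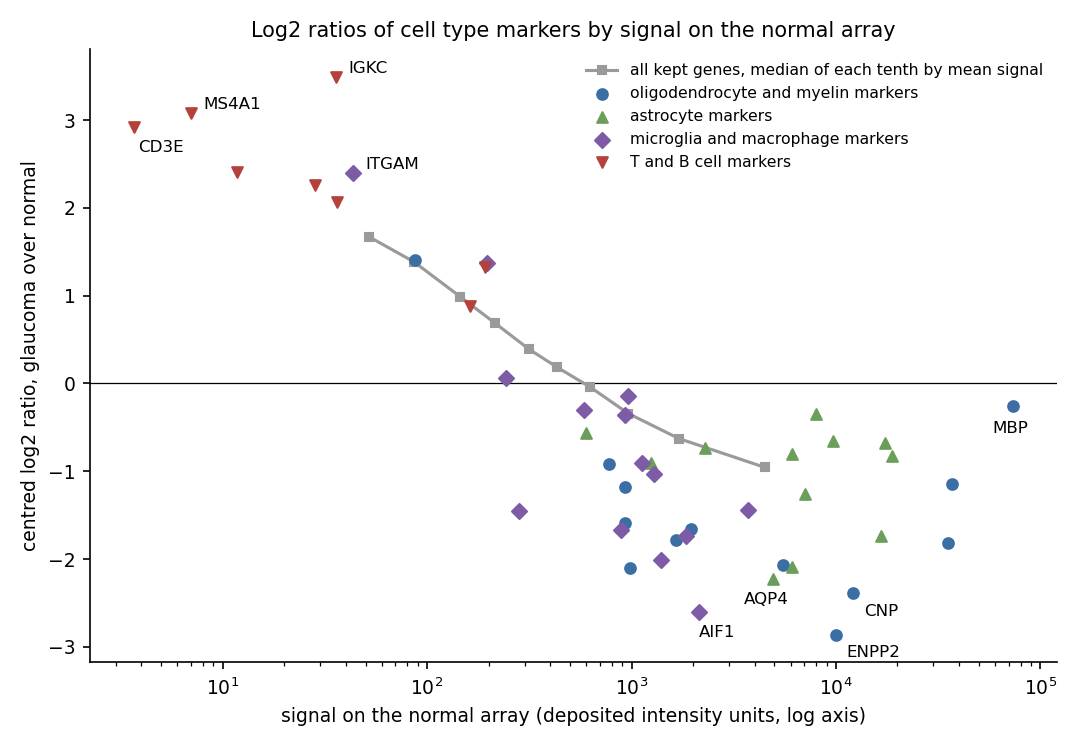
Centred log2 ratio of glaucoma over normal (vertical axis) against the signal on the normal array (horizontal log axis, deposited intensity units), with 1 point per kept marker gene of 4 cell type lists, and grey squares for the medians of all kept genes in 10 bins of mean signal. The bins run from 1.67 down to -0.96, the myelin markers from 1.40 down to -2.86, and the T and B cell markers from 3.49 down to 0.88.

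Oligodendrocytes wrap the axons behind the lamina in myelin. Of 13 kept oligodendrocyte and myelin genes, 10 were at least 2-fold lower on the glaucoma array, 1 was higher and 2 were within 2-fold. The list's median log2 ratio was -1.65, against -0.63 for matched random lists, at percentile 0.01. The ACTB control's 3' over 5' signal ratio, a measure of RNA integrity, was 7.58 on the normal and 21.3 on the glaucoma array. ENPP2, which encodes autotaxin, had a signal of 10054 on the normal and 1487 on the glaucoma array (log2 ratio -2.86), and CNP, a myelin phosphodiesterase, had 12157 and 2546 (log2 ratio -2.39). The receptor gene GPR37 (log2 ratio -2.10) and the myelin proteolipid gene MAL (log2 ratio -2.07) were also lower. MBP, the major basic protein of myelin, had 73512 and 68842, a log2 ratio of -0.26 that was 0.98 after loess, and its other probe sets reached -2.77. In the smaller set of 8 genes with probe sets free of a cross-hybridisation suffix, the list no longer stood apart (median -1.29, percentile 3.36).

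Of 5 kept oligodendrocyte precursor genes, 2 were at least 2-fold lower and 1 was higher, with a median of -0.88 at percentile 12.1. SOX10, the transcription factor of the oligodendrocyte lineage, went from 1568 to 120.9, which is below the highest trpn control signal (log2 ratio -3.25). PTPRZ1 had a log2 ratio of -2.12, OLIG2 -0.88 and the proteoglycan gene CSPG4 1.69. The 4 kept Schwann cell genes had a median of -0.24 at percentile 34.5, and -0.12 after quantile normalisation, with PMP2 at -1.34, ERBB3 at -1.0, PRX at 0.68 and CDH19 at 0.53.

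Microglia and macrophage genes were lower as a group. Of 14 kept members, 7 were at least 2-fold lower, 2 were higher and 5 were within 2-fold, and the median was -0.97 against -0.10 for matched lists (percentile 0.34). AIF1, which encodes the microglial protein IBA1, had a signal of 2136 on the normal and 335.6 on the glaucoma array (log2 ratio -2.60), with all 3 of its probe sets at or below that ratio. The fractalkine receptor gene CX3CR1 (log2 ratio -2.01) and the complement gene C1QB (log2 ratio -1.74) were lower as well. ITGAM, an integrin gene of myeloid cells, had a log2 ratio of 2.39 on its brighter probe set and -2.03 on another. With the median of all probe sets per gene, the list's median was -0.67 and its percentile 3.58, which no longer stood apart.

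Of 11 kept MHC class II genes, whose products present antigen to helper T cells, 7 were at least 2-fold lower and 2 were higher. Their median was -1.32 against -0.36 for matched lists, at percentile 0.40. HLA-DRA went from 2359 to 98.9, which is below the highest trpn control signal (log2 ratio -3.99), and CD74, the invariant chain, from 3776 to 863.4 (log2 ratio -2.20). The dimmer genes CIITA, the master regulator of the class, and HLA-DOA had log2 ratios of 2.40 and 1.72. The list did not stand apart after quantile normalisation (median -0.70, percentile 4.30) or loess (median -0.59, percentile 4.60). Of 10 MHC class I genes, 1 was at least 2-fold higher (TAP2, 2.81), 1 was lower (HLA-B, -2.76) and 8 were within 2-fold. Their median of -0.12, at percentile 76.8, had a positive sign under the other 3 scalings.

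T and B cell genes were higher, from very low signals on the normal array. Of 8 kept members, 7 were at least 2-fold higher and 1 was within 2-fold, with a median of 2.34 against 1.11 for matched lists (percentile 98.4), and 1.44 after loess. Of these 8, 7 were below the array median on the normal array and so were kept through the glaucoma array alone. Over all 15 measured T and B cell genes, without the filter, the median was 1.52 (percentile 99.2 of matched lists), and it lay at percentile 96.55 of equal draws from 51 genes of unrelated organs, whose own median was 0.97. IGKC, the immunoglobulin kappa constant gene, went from 35.7 to 1283 (log2 ratio 3.49, with another probe set at 1.03), and the B cell antigen gene MS4A1 from 7.0, below the highest trpn control signal, to 676.2 (log2 ratio 3.08). The T cell receptor subunit gene CD3E had a log2 ratio of 2.93 and IGHM one of 2.41. Beside these, haemoglobin beta (HBB) went from 552.8 to 3455 (log2 ratio 2.34) and the erythrocyte carbonic anhydrase gene CA1 had a log2 ratio of 2.18. These were the 2 kept erythroid genes, too few for a list value. The 5 kept neutrophil genes had a median of -0.11 at percentile 24.4, which was 0.05 as deposited, -0.75 after quantile normalisation and -1.05 after loess. Among them S100A8 was at 2.03 and FPR1 at -1.51.

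Astrocyte markers were lower by no more than genes of the same brightness. Of 12 kept members, 4 were at least 2-fold lower and 8 within 2-fold, with a median of -0.81 against -0.89 for matched lists (percentile 64.6), and -0.13 after loess. The water channel gene AQP4 went from 4931 to 1124 (log2 ratio -2.23), the aldolase gene ALDOC had a log2 ratio of -2.09, the gap junction gene GJA1 -1.73 and SOX9 -1.27, with another SOX9 probe set at 0.33. After loess AQP4 was at -1.39, ALDOC at -1.17, GJA1 at -0.65 and SOX9 at -0.25. Reactive glia genes were mixed. Of 17 kept members, 5 were at least 2-fold higher, 6 lower and 6 within 2-fold. Their median of -0.49, at percentile 35.0, was 0.03 after quantile normalisation and 0.12 after loess. GFAP, the intermediate filament gene of astrocytes, had a signal of 58238 on the normal and 11313 on the glaucoma array (log2 ratio -2.52), and after loess -1.35. NES was at -2.32, the small heat shock gene HSPB1 at -4.26 and CHI3L1 at 2.06.

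Neuron and axon genes had a median of -0.11 at percentile 29.5, which was 0.05 as deposited and 0.02 after loess. Of 11 kept members, 4 were at least 2-fold higher and 3 lower. NEFL, the light neurofilament gene, had 201.8 and 212.1 (log2 ratio -0.11), with 0.05 as deposited. The tubulin gene TUBB3 was at -1.71, and the synaptic gene SYT1 at 1.91, SNCG at 1.26 and the growth cone gene GAP43 at 1.24 on dimmer probe sets. GAP43 was near no difference (-0.09) with probe sets free of a suffix.

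**Figure D2:**
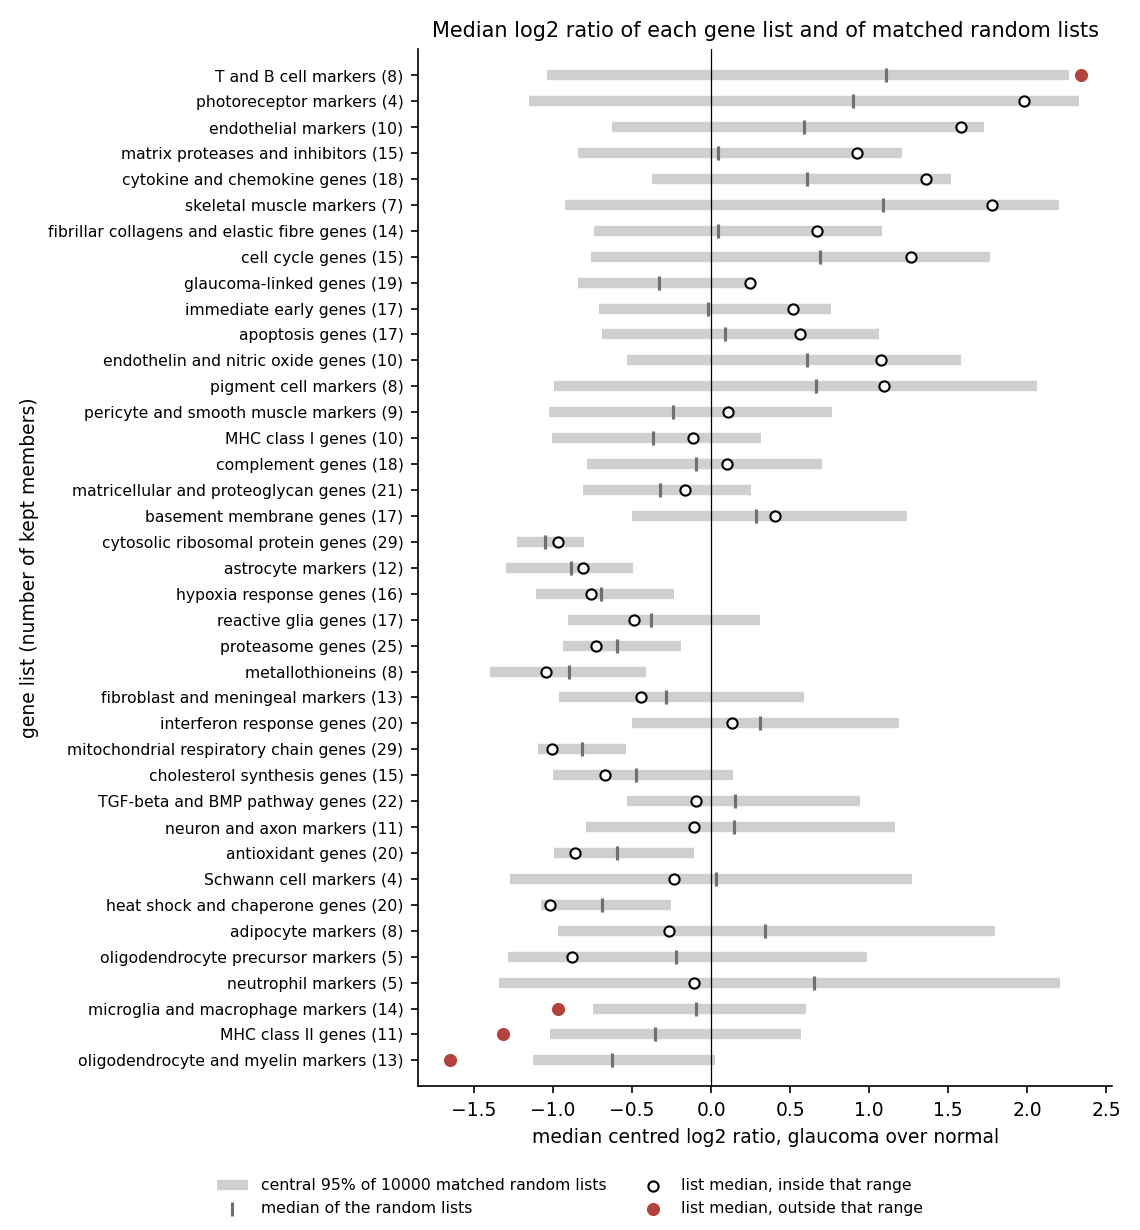
Median centred log2 ratio of each of 39 gene lists (circles, horizontal axis) with the median (ticks) and the central 95% (grey bars) of 10000 random lists matched on mean signal; the vertical axis names the lists with their number of kept members, ordered by distance from the matched median. The filled circles outside the bars are the oligodendrocyte and myelin (-1.65), MHC class II (-1.32), microglia and macrophage (-0.97) and T and B cell (2.34) lists.

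Endothelial genes were mostly higher, with 6 of 10 kept members at least 2-fold higher and 2 lower, and a median of 1.58 at percentile 94.8. After quantile normalisation the percentile was 98.5 (median 1.26), and after loess the median was 0.95. FLT1 (log2 ratio 2.64), ERG (2.63), ROBO4 (2.40) and EMCN (1.89) were all below 50 signal units on the normal array, and other probe sets of FLT1 and ERG had ratios of -0.97 and -0.69. Pericyte and smooth muscle genes had a median of 0.10 at percentile 74.4, with signs that differed between scalings, and TAGLN (-1.99), MYH11 (-1.43) and ACTA2 (-1.0) were lower while DES (1.97) was higher. Of 13 fibroblast and meningeal genes, 4 were at least 2-fold lower and 2 higher, with a median of -0.44 at percentile 32.4, which stood apart after quantile normalisation (median -0.72, percentile 2.31). PTGDS, the prostaglandin D synthase gene of the meninges, went from 55666 to 4225 (log2 ratio -3.86), with all 3 probe sets at or below -3.08, and COL1A1 had a log2 ratio of 2.41.

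Matrix genes build the plates of the lamina. Of 14 kept genes of fibrillar collagens and elastic fibres, 4 were at least 2-fold higher, 3 lower and 7 within 2-fold, with a median of 0.67 at percentile 88.9 (0.12 after loess). Among them FBLN1 was at 3.01, although its probe sets disagreed down to -2.75, FBN2 at 2.59 and EFEMP1 at -1.58. Of 17 basement membrane genes, 5 were higher, 2 lower and 10 within 2-fold (median 0.41, percentile 61.2, and 0.057 after loess), with LAMA1 at 1.61, COL4A6 at 1.45, LAMB3 at 1.43 and COL4A4 at -1.69. Of 21 matricellular and proteoglycan genes, 7 were higher and 5 lower (median -0.16, 0.27 after quantile normalisation, percentile 70.7). Thrombospondin 1 (THBS1) was at 3.37 and TNXB at 2.53, and the link protein gene of myelinated axons, HAPLN2, was at -3.10. CD44 was at -1.82 and 0.54 when all its probe sets were used. Of 15 matrix protease and inhibitor genes, 6 were higher and 4 lower (median 0.92, percentile 92.5, and 0.37 after quantile normalisation). ADAMTS2 was at 3.06, MMP7 at 2.78, MMP14 at 2.66 and MMP19 at 2.41. The normal signals of TNXB (19.9), ADAMTS2 (22.4) and MMP7 (10.9) were below the highest trpn control signal of 29.1. Those of MMP14 (111.5) and MMP19 (44.2) were below the array median of 162.9, so these genes were kept through the glaucoma array alone.

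Genes linked to glaucoma by inheritance or association were mostly within 2-fold. Of 19 kept members, 12 were within 2-fold, 4 were higher and 3 lower, with a median of 0.25 at percentile 97.0. CYP1B1, mutated in congenital glaucoma, went from 678.8 to 3266 (log2 ratio 1.99), and all 3 of its probe sets were at or above 1.06. COCH had a log2 ratio of 2.29, and MYOC, the myocilin gene, went from 61.8 to 351.1 (log2 ratio 1.5, and 0.56 after loess). OPTN, the optineurin gene, had 1735 and 1557 (log2 ratio -0.31), with 0.30 after quantile normalisation. The 22 genes of TGF-beta and BMP signalling had a median of -0.10 at percentile 23.4, which was 0.06 as deposited, with 5 higher and 4 lower. Among them were the follistatin gene FST (3.36), BMP5 (2.95), BMP6 (2.05) and ID3 (-2.44). The peptidylarginine deiminase genes, whose enzymes citrullinate proteins, had 2 kept members, PADI2 at -1.64 and PADI1 at 2.05.

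Immune signalling genes other than MHC class II did not stand apart. Of 18 cytokine and chemokine genes, 10 were at least 2-fold higher and 1 lower (median 1.36, percentile 93.4, and 0.65 after loess). IL1B was at 3.32, IL1A at 2.62, CXCL3 at 2.35 and CCL4 at 2.12. The normal signal of CXCL3 (17.2) was below the highest trpn control signal of 29.1. Those of IL1B (37.2), IL1A (52.9) and CCL4 (56.7) were below the array median of 162.9. Of 18 complement genes, 4 were higher and 5 lower (median 0.10, percentile 69.5, and 0.38 after quantile normalisation). CLU, the clusterin gene, went from 60831 to 21617 (log2 ratio -1.65, and -0.45 after loess), C1QA was at -1.67 and CD46 at -2.0, with another CD46 probe set at 0.92. Of 20 interferon response genes, 5 were higher and 7 lower (median 0.13, -0.30 after quantile normalisation, percentile 34.5), with CXCL10 at 2.56, IFITM3 at -2.57, IFIT1 at -1.91 and IFIT2 at -1.80.

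Genes of protein folding, redox defence and energy supply were lower together with other bright genes. After loess, which removes the trend with brightness, the medians below shrank to -0.35 for heat shock, -0.14 for antioxidant, -0.38 for metallothionein, -0.19 for respiratory chain and -0.28 for hypoxia response genes. Of 20 heat shock and chaperone genes, 10 were at least 2-fold lower and none was higher (median -1.02, percentile 4.62, and 1.84 after quantile normalisation), with HSPB1 at -4.26 and the lens and glial chaperone CRYAB at -1.94. HSP90B1 was at -2.84 with another probe set at 2.52. Of 20 antioxidant genes, 8 were lower and 1 higher (median -0.86, percentile 9.54), with GPX4 at -2.08, GPX1 at -1.99 and GSR at 2.11. The 8 metallothioneins (median -1.04, percentile 28.5) included MT1X at -2.07 and MT3 at -1.49. The 29 respiratory chain genes (median -1.0, percentile 9.89) included UQCRC1 at -2.53 and COX5A at -1.96. Of 16 hypoxia response genes, 6 were lower and 2 higher (median -0.76, percentile 38.5), with ALDOA at -2.94 and the vasodilator gene ADM, from 1146 to 5097, at 1.92. The 29 ribosomal protein genes had a median of -0.97 at percentile 72.7, which was 0.12 after quantile normalisation, with RPL8 at -2.66.

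Many of the largest ratios were in genes that were near background on one of the arrays. Among genes that met the naming rule, the largest lower ratios were those of EIF3G (-4.50), CCDC92 (-4.30), HSPB1 (-4.26), ABHD17A (-4.13), PLTP (-4.12), CSDC2 (-4.10), GPI (-4.05), COPE (-4.02), HLA-DRA (-3.99), RCN2 (-3.94, with another probe set at -0.99), PSMB3 (-3.90), PTGDS (-3.86), TST (-3.81), MTHFD2 (-3.73) and TTYH1 (-3.68). In 14 of these 15 genes the glaucoma signal was below 198.5, the highest signal of the trpn control. Under the same rule, the largest higher ratios were those of MEFV (5.17), SCD5 (4.73), ALDH1B1 (4.58), PNO1 (4.11, another probe set 0.29), SLC19A3 (4.03), DNAH3 (3.90), IFNA10 (3.85), GLE1 (3.76), SLC30A5 (3.72, another 0.26), SH2D1A (3.70), LRRC37BP1 (3.69), POLR2J4 (3.62), TCTN2 (3.61), WEE1 (3.60, another 1.11) and USP18 (3.59). In 8 of these 15 the normal signal was below 29.1, the control's highest there, so the ranks on either side are not exact. Of the 15 genes on either side, 12 had only 1 kept probe set, so no other probe set could bear on their ratios. Of the 15 higher genes, 8 were read by probe sets with the suffix x_at, marked as prone to cross-hybridisation. This class made up 8.34% of kept genes and 13.9% of genes at least 4-fold higher. It is narrower than the lettered suffixes left out in the alternative without suffixed probe sets. SCD5, a fatty acid desaturase gene, went from 829.2 to 26598.

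The control transcripts of both tissue and spike-in RNA differed between the arrays. The 3' over 5' signal ratio, which grows when RNA is broken or labelled incompletely, was 7.58 for ACTB on the normal and 21.3 on the glaucoma array, and 2.67 and 5.23 for GAPDH. For the 4 bacterial poly-A spike-ins it was higher on the glaucoma array as well, with 2.09 and 9.08 for dap and 1.12 and 2.43 for lys. The gene probe set of ACTB had a log2 ratio of -1.52 and that of GAPDH -2.05, and both stayed negative after quantile normalisation (-0.67 and -1.10) and loess (-0.35 and -0.91). The highest trpn control signal lay above 5.35% of kept genes on the normal and 11.1% on the glaucoma array.

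**Figure D3:**
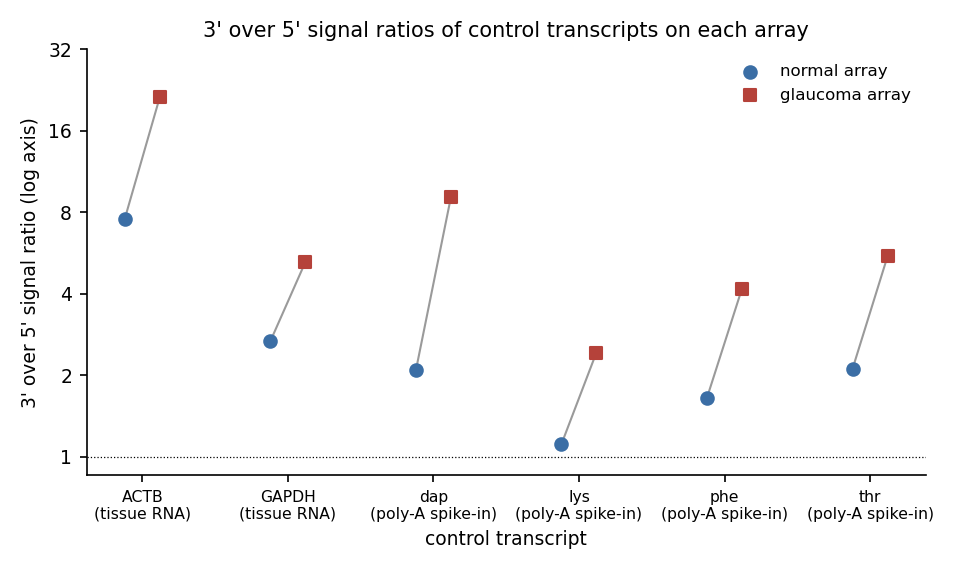
Ratio of 3' to 5' probe set signal (vertical log axis) of 6 control transcripts (horizontal axis) on the normal array (circles) and the glaucoma array (squares), with a line joining the same transcript. Every ratio was higher on the glaucoma array, from 2.43 for lys to 21.3 for ACTB, against 1.12 and 7.58 on the normal array.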

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

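The tests weighed here were all chosen after the results were seen.

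Signals of the array's own controls, which no gene comparison uses, differed between the arrays. The probe set for the Alu repeat, a sequence scattered through introns and intergenic DNA, had a signal of 83883 on the normal array and 209566.1 on the glaucoma array, a fold of 2.5. The 18 probe sets of the hybridisation spike-ins bioB, bioC, bioD and cre were brighter on the glaucoma array by a median fold of 3.678, with a range from 1.71 to 5.63. The 3' over 5' ratios of the poly-A spike-ins dap, lys, phe and thr were higher there by a median fold of 2.56.

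Among kept genes, bright ones were lower and dim ones higher on the glaucoma array. The filter contributes to the higher ratios of dim genes, as many of them were kept through the glaucoma array alone. Breakdown of the tissue RNA as the whole cause of the higher 3' over 5' ratios is argued against by the bacterial spike-ins, whose ratios were higher by a median of 2.56-fold, beside 2.80-fold for ACTB and 1.96-fold for GAPDH, though the step at which the spike-ins were added is not recorded. Less labelled tissue target on the glaucoma array, made up for by the scaling, is a candidate explanation that needs brighter hybridisation spike-ins, and their median log2 ratio was 1.879, unless the amounts added differed. Labelled target that carries repeats, such as genomic DNA or unspliced RNA, may also contribute. The Alu control lay at percentile 99.5 of the 200 probe sets nearest to it in mean signal. The match is poor, since its 83883 on the normal array was close to that array's highest signal of 84515. Its fold of 2.5 was also below the median of 3.678 for the hybridisation spike-ins, so the percentile cannot decide this. Disease, donor and array cannot be separated with 1 array per group, so an effect of glaucoma on this pattern stays open and untested.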

How the results depend on the processing

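The alternative that raised signals below the array median to it was chosen after seeing the data, and the other 9 were fixed before. The list of T and B cell genes stood apart in all 9 settings that gave it a value (the main one included). The myelin and the microglia lists each did in 10 of 11, and the MHC class II list in 9 of 11. Values as deposited differ from the main ones by a constant, and list percentiles there repeat the main setting apart from the random draws. For T and B cell genes the percentile was 98.57 as deposited and 98.38 in the main setting. The deposited setting is therefore no separate check in these counts. For single named genes, 1568 of 1739 alternative values stayed within the probe set error of the main value and 165 moved further. Another 6, of genes at least 2-fold apart in the main setting, took the other sign. Of the 12 named genes within 2-fold in the main setting, 6 had 11 values of the other sign, counted by distance alone. The probe set error of 1.09 log2 units is larger than 2-fold, so a gene value within it need not be stable. Gene values as deposited also differ by a constant and are no separate check. Of 377 alternative values of lists, 358 kept their side of the bounds, among them those as deposited, which are no separate check. Another 13 could not be had for 10 lists with under 4 members left, at the 75th percentile or without suffixed probe sets. Unless said otherwise, the cause of a difference was not tested.

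A pseudocount at the median signal gave 1578 genes higher and 1221 lower, as a larger pseudocount shrinks ratios. The filter at the 75th percentile (4917 genes) gave 1258 and 743, and probe sets without a suffix (5476 genes) gave 1588 and 1195, with fewer genes counted. As deposited, 64.1% of genes past 2-fold were higher, against 56.4% in the main setting, 51.6% after quantile normalisation and 48.6% after loess. Same-sign pairs made up 57.5% after quantile normalisation, 57.0% after loess, 58.9% without a filter, 58.0% without suffixed probe sets and 64.4% with low signals raised.

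Quantile normalisation brought out endothelial (median 1.26), fibroblast and meningeal (-0.72), heat shock (-0.51) and cholesterol synthesis genes (-1.01), and ended the call of MHC class II genes (-0.70). Loess brought out cholesterol synthesis genes (-0.82) and ended the MHC class II call (-0.59). The filter at the 75th percentile brought out reactive glia (-0.78), oligodendrocyte precursor (-1.09), fibrillar collagen and elastic fibre (1.06) and immediate early genes (0.81). The median of all probe sets brought out oligodendrocyte precursor genes (-1.51) and ended the microglia call (-0.67). Without suffixed probe sets the myelin call ended (-1.29), oligodendrocyte precursor genes stood apart (-1.56), and endothelin and nitric oxide genes turned from higher to lower (-1.35). Endothelial genes (1.06) stood apart with the median pseudocount, heat shock genes (-1.22) without a filter, and glaucoma-linked genes (0.36) without a pseudocount.

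Among named genes at least 2-fold apart, FBLN1 (-0.52), CD44 (0.54) and RPL18 (0.033) took the other sign with the median of all probe sets, GAP43 (-0.093) without suffixed probe sets, and CFD (0.092) and COL4A4 (0.44) with low signals raised. Among those within 2-fold, MBP (0.98), OPTN (0.37), HLA-C (0.29) and PRX (-0.004) did after loess, NEFL (0.053) as deposited, and FCGR3B (0.47) with low signals raised. Dim signals limit the rest, as 11.1% of kept genes lay below the highest trpn control signal on the glaucoma array. No paired analysis was possible because each group has 1 array and no test was run, and for the same reason no replicate could be left out.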

Other observations

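The tests below were chosen after the results were seen, except that of a raised floor for the T and B cell genes, whose prediction was written before its result.

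Genes of proliferation, cell death, vascular tone and the immediate early response did not stand apart from genes of similar brightness in the main setting. Of 15 kept cell cycle genes, 9 were at least 2-fold higher and 3 lower (median log2 ratio 1.27, percentile 81.3, and 0.36 after loess). The mitotic kinase gene BUB1 was at 2.39, where all 4 probe sets were at or above 2.02, BIRC5 at 2.32, MKI67 at 2.09 and RRM2 at 2.02. Their normal signals were low, with 46.3 for BUB1, 55.9 for RRM2, and 12.2 for BIRC5 and 23.6 for MKI67, both below the highest trpn control signal. Dim kept genes were higher as a whole (median 1.67 in the dimmest 10%). Agreement of the BUB1 probe sets therefore cannot tell a change of the gene from that rise. Of 17 apoptosis genes, 7 were higher and none was lower (median 0.56, percentile 86.0, and 0.37 after loess). BCL2L11 was at 2.38 and the death receptor gene FAS at 1.82, while XIAP was at 2.75 on 1 probe set and -0.98 on the other. The normal signals behind the higher ratios of BCL2L11 (4.0) and XIAP (3.2) were below the highest trpn control signal of 29.1. Of 10 genes of endothelin and nitric oxide signalling, 5 were higher and 4 lower (median 1.07, percentile 79.0, and 0.46 after loess), but the median was -1.35 (percentile 0.545) without suffixed probe sets. They included the angiotensin receptor gene AGTR1 at 2.59, NOS1 at 2.07, the endothelin gene EDN1 at -1.98 and AGT at -1.86. Of 17 immediate early genes, 5 were higher and 2 lower (median 0.52, percentile 92.2), with NR4A1 at 2.52 and another NR4A1 probe set at -0.78, EGR3 at 1.79, JUND at -1.99 and FOS at -1.61.

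Cholesterol synthesis supplies the lipid of myelin. Of 15 kept genes, 6 were at least 2-fold lower and 1 higher (median -0.67, percentile 25.4), and after quantile normalisation the median of -1.01 lay at percentile 0.07. DHCR7 was at -2.66, MSMO1 at -2.20, SC5D at -1.65 and INSIG1 at -1.52. Of 25 proteasome genes, 8 were lower and 1 higher (median -0.73, percentile 23.0, and -0.11 after loess), with PSMB3 at -3.90, PSMD8 at -2.74, PSMC4 at -2.65 and PSMB2 at 4.0 on one probe set and -0.90 on the other. Markers of tissues around the nerve did not stand apart. The 4 kept photoreceptor genes had a median of 1.98 (percentile 91.8, 1.06 after loess, CNGA1 2.77, PRPH2 2.41), the 8 pigment cell genes 1.09 (percentile 66.4, 0.61 after loess, MLANA 2.44, TYR 2.40), the 7 skeletal muscle genes 1.78 (percentile 86.0, 0.91 after loess, TNNT3 2.01) and the 8 adipocyte genes -0.26 (percentile 20.6, -0.67 after loess, 4 above and 4 below 0, GPD1 -2.0, PCK1 1.99). The 3 kept epithelial genes, too few for a list value, were ELF3 (2.57), KRT18 (1.85) and KRT8 (0.81). The normal signals of CNGA1 (11.1), MLANA (2.5) and ELF3 (22.5) were below the highest trpn control signal of 29.1.

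Oligodendrocyte and myelin genes were lower on the glaucoma array. A trend of the log2 ratio with mean signal as the whole cause is argued against by the main setting. There the list lay at percentile 0.01 of random lists matched on mean signal. After loess on the same mean signal, its median of -1.17 lay at percentile 0.0 of matched random lists. Because both steps use mean signal, the loess result is no separate check. A lower share of nerve tissue of every kind in the piece would lower astrocyte and myelin markers alike, but after loess the difference of the myelin from the astrocyte median was -1.04 on the log2 scale, at percentile 0.07 of differences between matched lists. That the glaucomatous nerve held fewer oligodendrocyte transcripts may remain as a hypothesis. A different level of dissection along the nerve, where myelin starts behind the lamina, and a difference between donors or arrays were not tested and stay open.

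T and B cell genes were higher on the glaucoma array. A raised floor of genes that are not expressed is a candidate explanation. Of 51 measured genes of liver, pancreas, kidney, testis and other organs, 24 were at least 2-fold higher without a filter, with a median of 0.97, and the median of 1.52 over 15 T and B cell genes lay at percentile 96.55 of equal draws from them, below the bound set beforehand. Blood in the glaucoma piece stays open, because HBB had a log2 ratio of 2.335 while the neutrophil list lay at percentile 24.4 (15.1 after loess), and lymphocytes in the glaucomatous tissue were not tested apart from it.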
